A study of Mus musculus with 45 samples.

How the data were processed

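RNA was measured by sequencing in the cortex, hippocampus and retina of mice of both sexes, aged 3 months, that had received tamoxifen or its sunflower oil vehicle. Tamoxifen is an oestrogen receptor modulator that is widely used in mice to switch on tamoxifen-dependent forms of Cre recombinase. Per the labels' protocols, DNA and RNA were extracted together with AllPrep kits and libraries were made with a TruSeq RNA kit.

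The authors deposited 1 table per tissue that holds estimated counts per gene, marked as raw in the column names, with fractional parts. RefSeq was the source of the gene models, per the file headers. The submitters' processing notes name the builds GRCm38 and mm10 and the tool DESeq, without saying what each was used for. The aligner, the counting program, their versions and the use of strand are not given in the sources used here. Near-identical gene copies, overlapping genes and antisense partners can therefore share reads, and values of such genes are uncertain. Each table listed 36172 genes, of which 32891 had a gene ID that matched the RefSeq gene table used for older symbols. Genes carried by the mitochondrial genome were not analysed here. Coordinates are those of the deposited tables, taken to be on GRCm38 (mm10), the build in the submitters' processing notes.

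Columns were matched to samples by the animal number in each title, and groups were taken from the sex and treatment labels. The values were expected counts, so they were rounded to whole numbers before testing. Of the nonzero deposited values in the cortex, 23.4% were whole to within 0.001. The same animal number appears in the titles of all 3 tissues, so the libraries of different tissues came from shared animals and each tissue was tested on its own. Replicates are separate animals. No pair of libraries within a group agreed within sampling noise, as chi-square per gene between replicates was at least 3.05.

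Total counts ranged from 10259768 to 22375163 in 14 cortex libraries, from 31154309 to 44153244 in 14 hippocampus libraries and from 9143811 to 18253874 in 15 retina libraries. A further cortex library, from male tamoxifen animal 962, held 4567 counts. It was left out because its total lay under 1000000, a limit set after its depth was seen and before any test was run. The plan had included all 15 cortex libraries, and counts from that fit are printed beside the cortex results. The hippocampus of animal 965 was not analysed here. Intervals and floors given for counts cover counting error alone.

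Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total count 15), libraries were scaled by TMM, and each tissue was fitted with edgeR's quasi-likelihood model (edgeR 4.0.16 in R 4.3.3) with 1 mean for each of the 4 groups of sex and treatment. The contrasts were tamoxifen against vehicle averaged over the sexes, the same in females and in males, the difference between these effects (male minus female), and male against female averaged over treatments. P-values were adjusted by the Benjamini-Hochberg method over the genes tested in a tissue, with a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. CPM values are counts scaled to the TMM-adjusted library size unless a table total is named. A joint fit of all tissues with 12 group means tested with 2 degrees of freedom whether the sex-averaged effect differed between tissues.

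Gene lists for cell types, pathways and sex-linked genes were tested with limma's camera (limma 3.58.1, log2 CPM with a prior count of 2) at a preset inter-gene correlation of 0.01, adjusted over 160 tests per tissue for the treatment contrasts and over 40 lists for sex. Of 703 list genes, 16 were matched through the gene ID under an older symbol and 14 were not found in the tables, 13 of them mitochondrial. The fry test was run beside camera. With the preset correlation, lists also passed for tamoxifen in other splits of the libraries into treatment groups of the same sizes. Of 100 splits with the real one, 99 others passed at least 1 list in the cortex, 99 in the hippocampus and 98 in the retina. A pass with the preset correlation alone therefore does not set treatment apart from other groupings.

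Before the data were examined, the lists, the main design, the alternatives and the rule for naming genes were fixed. The rule took all genes past the threshold in a contrast if there were at most 20, and otherwise the 10 with the largest rise and the 10 with the largest fall, leaving out predicted genes and clones beyond the first 3 of a direction. Where fewer than 5 passed, it added the 5 with the smallest unadjusted p as values that did not pass. From each list it took up to 4 members with the smallest p, and in every tissue it took Xist, Ddx3y, Eif2s3y, Kdm5d, Uty, Esr1, Gper1, Pgr, Greb1, Hmgcs1, Sqle, Gfap and Aif1. Some genes that the rule takes, and some past the joint test, are not reported here. The chaperone gene Hspa5 and the tissue markers Ttr and Cryaa are named beside the rule.

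The alternatives were DESeq2 1.42.0, DESeq2 size factors in place of TMM, no filter on low counts, a stricter filter at a mean of 1 CPM, fits on the contrasted groups alone or an additive model, leaving out each animal in turn, an estimated inter-gene correlation, and animal as a block in the joint fit. For the joint test DESeq2 was run as a likelihood ratio test, because its Wald test covers 1 contrast at a time. Another pseudocount was not tried because the values were counts. Fits without libraries rich in choroid plexus or lens transcripts, without a pair of retina libraries that stood apart, and with the mean level of rod genes as a covariate were added after seeing the data. Over shared animals, deviations from the group means correlated with a median r of 0.077 between cortex and hippocampus, 0.046 between cortex and retina and -0.029 between hippocampus and retina. The pairing itself comes from the animal numbers in the titles.

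The gene tests were tested on simulated data drawn from the real means, library sizes and spread. With sexes averaged, genes changed by 1.5-fold were recovered in 79.8% of cases in the cortex (14575 genes), 81.8% in the hippocampus (15230 genes) and 77% in the retina (14671 genes). For genes changed by 2-fold the shares were 91%, 95% and 89%, and false calls made up 4.26%, 3.57% and 7.25% of calls. The simulated data gave 188, 196 and 193 calls in the 3 tissues, against 89, 10 and 7 in the real data. With fewer calls the adjusted threshold is stricter, and the simulated libraries had no structure beyond their groups. The recovered shares are therefore not the power of the real tests. In the joint test on 13790 simulated genes 90% of genes changed by 2-fold were recovered, and 13.9% of calls were false, above the threshold of 0.05. With the animal block this share was 10.9%, and the share in the retina also lay above the threshold.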

Results

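RNA was compared between tamoxifen and vehicle in the cortex, hippocampus and retina of male and female mice. In the cortex, 4 female tamoxifen, 3 female vehicle, 3 male tamoxifen and 4 male vehicle libraries entered the tests. The hippocampus had 4, 3, 4 and 3 libraries in the same order, and the retina had 4, 3, 4 and 4. The sex labels were checked first with Xist, the RNA that silences an X chromosome, and with Y-linked genes. Xist lay between 343 and 574 CPM (counts scaled to a library total of 1000000) in the 7 female cortex libraries and at most 0.975 CPM in the 7 male ones. Ddx3y, a Y-linked RNA helicase, lay between 53.7 and 67.6 CPM in male cortex and at most 0.179 CPM in females. In the retina Xist was at least 1180 CPM in females and at most 4.97 CPM in males, and in the hippocampus at least 297 CPM against at most 0.752 CPM. All libraries tested thus carried the sex-linked transcripts of their label.

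The first question was which genes differed with tamoxifen in the cortex. Immediate early genes, which cells transcribe rapidly after stimulation, were higher with tamoxifen in both sexes. Fos, a subunit of the AP-1 transcription factor (gene ID 14281, chromosome 12, 85473901 to 85477270), averaged 98.3 ± 9.31 CPM (SD, n = 4) in tamoxifen females and 57.4 ± 6.07 (SD, n = 3) in vehicle females. In males Fos averaged 78.5 ± 5.72 CPM (SD, n = 3) with tamoxifen and 48.6 ± 2.26 (SD, n = 4) with vehicle. The sex-averaged log2 fold change of Fos was 0.73 ± 0.06 (SE, adjusted p = 4.21e-07). Zbtb16, a zinc finger repressor whose transcription responds to glucocorticoids (gene ID 235320, chromosome 9, 48654297 to 48835945), fell by 0.78 ± 0.06 on the log2 scale (SE, adjusted p = 1.85e-07), from 60.1 ± 4.21 to 36.4 ± 2.69 CPM in females and from 69.8 ± 5.64 to 38.9 ± 2.54 CPM in males. Fos lay above, and Zbtb16 below, every same-sex vehicle library in 7 of 7 tamoxifen libraries.

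Across 14680 genes tested in the cortex, 89 passed the threshold, 29 higher and 60 lower with tamoxifen. The other genes with the largest rises were Cyr61, a matricellular protein (0.91 ± 0.14), the transcription factors Egr2 (0.88 ± 0.09) and Junb (0.78 ± 0.10), the antiproliferative factor Btg2 (0.66 ± 0.09), the orphan nuclear receptor Nr4a1 (0.59 ± 0.07), Ier2, the kinases Sik1 and Hunk, and the MAP kinase phosphatase Dusp1 (0.49 ± 0.05; log2 fold change ± SE). The largest falls were in Plin4, a coat protein of lipid droplets (-1.13 ± 0.22), Serinc2 (-0.79 ± 0.16), the kinase Sik2 (-0.55 ± 0.08), the nuclear matrix protein Banp (gene ID 53325, chromosome 8, 121950533 to 122029258; -0.53 ± 0.08), the glucocorticoid receptor co-chaperone Fkbp5 (-0.53 ± 0.08), the synaptic adhesion protein Lrfn2, the clock gene Per2 (-0.49 ± 0.06), the orphan receptor Nr6a1 and the glycolytic regulator Pfkfb3 (-0.47 ± 0.06). Of these, Nr6a1 had the largest adjusted p, 0.0455. Leaving out 1 library ended the call of Ier2 (without animal 958, adjusted p = 0.0517), of Plin4 (without 954, 958 or 961, up to 0.11), of Serinc2 (without 952, 954, 957, 958, 959, 961, 964 or 965, up to 0.11) and of Nr6a1 in every fit but those without 959 or 966 (up to 0.149). DESeq2 called 176 genes, among them all 89. With the near-empty library included the count was 71, and without the libraries rich in the choroid plexus transcript Ttr it was 35 (19 higher and 16 lower), without the excess of falls. The count moved by more than 1.5 times without animal 952 (47 genes), 954 (48), 957 (56), 958 (31) or 961 (51).

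**Figure D1:**
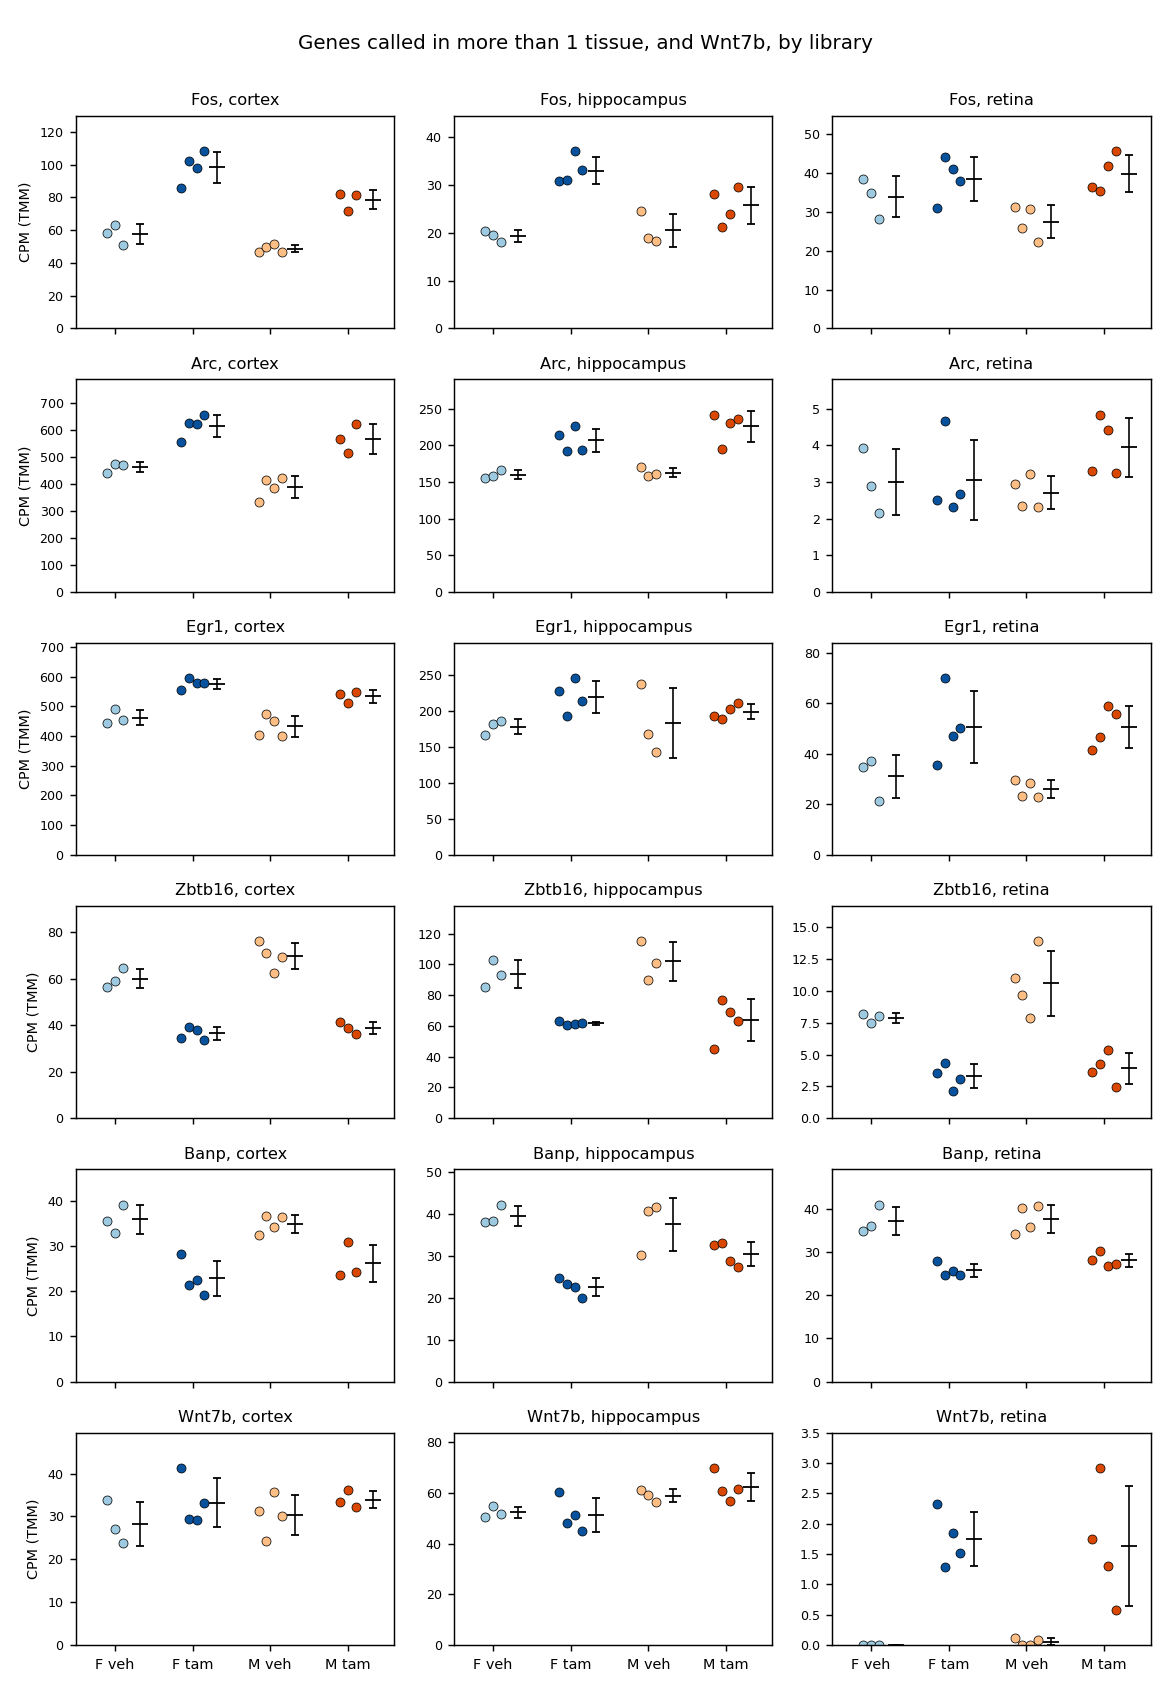
TMM-scaled CPM of 6 genes in each library (points) of the 4 groups of sex and treatment (F, female; M, male; veh, vehicle; tam, tamoxifen), 1 row per gene and 1 column per tissue, with mean and SD beside the points. In the retina, Wnt7b lies between 0.571 and 2.92 CPM in tamoxifen libraries and at most at 0.109 CPM in vehicle libraries.

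The immediate early gene list held 21 genes tested in the cortex, of which 13 rose when adjusted over all genes and 17 rose when adjusted over the list alone. Of the 21 fold changes 20 were positive, with a median log2 fold change of 0.46 (camera adjusted p = 1.6e-26, and adjusted p = 0.00992 with an estimated correlation). Arc, a synaptic protein made on neuronal activity, rose by 0.48 ± 0.05 (SE, adjusted p = 5.2e-05) and Egr1 by 0.31 ± 0.04. Among 26 genes of cholesterol synthesis and uptake, 2 rose over all genes and 4 adjusted over the list alone (camera adjusted p = 6.03e-05; adjusted p = 0.497 with an estimated correlation). Among them was Insig1 (0.24 ± 0.05, adjusted p = 0.019), a sterol-sensing regulator of the pathway. Among 19 glucocorticoid responsive genes Zbtb16, Fkbp5 and Plin4 fell and the clock gene Per1 rose (0.29 ± 0.05, adjusted p = 0.00999); the list as a whole did not pass (camera adjusted p = 0.0627). Adjusted over the list alone, 2 clock genes rose and 3 fell among 16; over all genes Per1 rose and Per2 and Bhlhe40 fell (camera adjusted p = 0.0475; adjusted p = 0.524 with an estimated correlation). The oestrogen receptor and response list did not pass (16 genes, median -0.04, camera adjusted p = 0.336).

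The next question was whether the sexes responded alike in the cortex. In females 15 genes were higher and 40 lower; in males Fos, Arc and Egr2 were higher and Zbtb16 lower, with Egr2 not past the threshold without animal 959 (adjusted p = 0.0564). The Zbtb16 log2 fold change was -0.72 ± 0.08 in females (SE, adjusted p = 0.000141) and -0.84 ± 0.08 in males (SE, adjusted p = 2.02e-05). Females also showed falls in Hif3a, a hypoxia-inducible factor subunit (-1.06 ± 0.20, adjusted p = 0.0179), and Zswim6 (-0.68 ± 0.09, adjusted p = 0.000553). P2ry2, a nucleotide receptor, lay between 0.809 and 1.27 CPM in tamoxifen females and at most at 0.166 CPM in vehicle females. The call of Hif3a held in 14 of 22 alternative fits (adjusted p up to 0.386) and ended without animal 952, 953, 954, 957 or 958 (up to 0.145). The call of P2ry2 ended without 955 or 958 (up to 0.121), and Zswim6 stayed past the threshold in 14 of 14 such fits. Of 18 genes of rod photoreceptors 17 had positive fold changes in tamoxifen females, 12 of them past the threshold adjusted over the list alone and 0 over all genes by edgeR (median 1.69, camera adjusted p = 3.87e-08; adjusted p = 0.497 with an estimated correlation). The test of the difference between the sexes called 0 genes by edgeR, with 808 at an unadjusted p under 0.05 and 7 by DESeq2; Zswim6 came closest (0.76 ± 0.12, adjusted p = 0.0661). Choroid plexus genes were lower with tamoxifen in females (17 genes, median -2.31, camera adjusted p = 0.00334; adjusted p = 0.798 with an estimated correlation) and higher in males (median 2.9, camera adjusted p = 0.0142; adjusted p = 0.798 with an estimated correlation), with Ttr at 1127 CPM in female vehicle animal 958 and 2702 CPM in male tamoxifen animal 960.

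The sex-specific cortex counts depended on the libraries. With the mean level of rod genes as a covariate 6 genes were called in females (5 higher and 1 lower, 3 of them shared with the 55), 7 in males and 1 for the difference, and without libraries rich in Ttr 13 in females (8 higher and 5 lower). Leaving out animal 952 gave 27 genes in females, 953 gave 30, 954 gave 24, 957 gave 36 and 958 gave 11 (6 higher and 5 lower). The excess of falls in females was not seen without 958, without libraries rich in Ttr or with the covariate. In the test of the difference, leaving out 951 gave 5 and 957 gave 2. DESeq2 called 101 genes in females and 29 in males. With all 15 libraries the counts were 43, 3 and 1 in females, males and the difference.

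**Figure D2:**
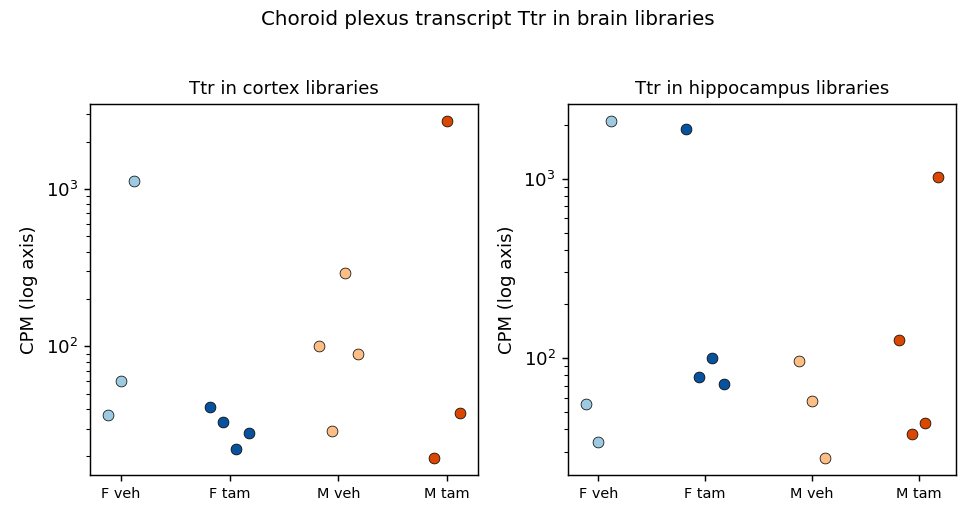
CPM of the choroid plexus transcript Ttr in cortex (left) and hippocampus (right) libraries, 1 point per library, on log axes, by sex and treatment. Ttr reaches 1127 CPM in female vehicle and 2702 CPM in male tamoxifen cortex, and 1900, 2092 and 1023 CPM in hippocampus libraries of animals 951, 958 and 962.

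In the hippocampus, Arc and Fos were higher and 8 genes lower with tamoxifen among 15339 tested. Arc averaged 207 ± 15.9 CPM (SD, n = 4) with tamoxifen and 160 ± 5.94 (SD, n = 3) with vehicle in females, and 226 ± 21.2 (SD, n = 4) against 163 ± 6.72 (SD, n = 3) in males (log2 fold change 0.42 ± 0.05, SE, adjusted p = 0.0125). Fos rose by 0.55 ± 0.09 (SE, adjusted p = 0.0242). Hif3a fell by 0.92 ± 0.13, Zbtb16 fell by 0.64 ± 0.09 and Banp fell by 0.55 ± 0.08 on the log2 scale (adjusted p = 0.0145 for each). The other genes that fell were the phospholipid flippase Atp10a (-0.57 ± 0.09), Nr6a1 (-0.49 ± 0.07), Cables1 (-0.45 ± 0.08), Sik2 (-0.41 ± 0.07) and the anion channel subunit Lrrc8c (-0.38 ± 0.07). Arc lay above, and Zbtb16, Nr6a1, Atp10a, Sik2 and Cables1 below, every same-sex vehicle library in 8 of 8 tamoxifen libraries. Fos lay above them in 6 of 8, and Lrrc8c lay below them in 7, Banp in 6 and Hif3a in 4. Arc and Banp stayed past the threshold with any 1 animal left out, and Hif3a and Zbtb16 with any but 952 or 957 left out (adjusted p up to 0.0601). The calls of Fos, Nr6a1, Atp10a, Sik2, Lrrc8c and Cables1 ended in 9, 7, 8, 10, 12 and 11 of 14 such fits, among them in each case those without 952, 957, 958 and 964, with adjusted p up to 0.174 for Lrrc8c.

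Among immediate early genes in the hippocampus 2 of 21 rose over all genes and 10 rose adjusted over the list alone (median 0.22, camera adjusted p = 6.91e-10; adjusted p = 0.777 with an estimated correlation). Of 19 glucocorticoid responsive genes Zbtb16 fell over all genes, and 6 fell adjusted over the list alone (camera adjusted p = 0.0104; adjusted p = 0.777 with an estimated correlation). Nuclear-encoded genes of oxidative phosphorylation had 31 of 32 positive fold changes, with a median of 0.08 (camera adjusted p = 2.64e-05; adjusted p = 0.886 with an estimated correlation). Genes of cholesterol synthesis and uptake did not pass as a list (median 0.01, camera adjusted p = 0.775).

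In hippocampus females Hif3a (-1.45 ± 0.19) and Banp (-0.81 ± 0.11) fell (SE, adjusted p = 0.0114 for both). The call of Hif3a ended without animal 952, 953, 954 or 957 (adjusted p up to 0.0734), and that of Banp without 952, 953, 954, 955, 957 or 958 (up to 0.103). In males edgeR called 0 genes, with 879 at an unadjusted p under 0.05 and 17 by DESeq2; Arc had the smallest p there (0.47 ± 0.08, adjusted p = 0.217). For the difference between the sexes edgeR called 0 genes, with 463 at an unadjusted p under 0.05 and 0 by DESeq2. DESeq2 called 63 genes with sexes averaged and 20 in females. Both edgeR counts were 0 (by edgeR's test) without the libraries rich in Ttr, those of animals 951, 958 and 962, while a choroid plexus score as covariate on all libraries gave 13 genes with sexes averaged. The sex-averaged log2 fold change of Arc stayed between 0.40 and 0.45 over 20 alternative fits and short of the threshold only without those libraries (adjusted p = 0.0594). The sex-averaged count of 10 fell to 2 without animal 952 or 957, 4 without 958, 5 without 953, 964 or 966, and 6 without 954, 955 or 961. The female count was 0 without 952, 953, 954 or 957, 1 without 955 or 958 and 5 without 959, and the male count was 1 without 960.

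In the retina, 7 of 14781 genes differed with tamoxifen, sexes averaged. Wnt7b, a secreted Wnt ligand (gene ID 22422, chromosome 15, 85535437 to 85581821), had 97 counts over the 4 female tamoxifen libraries (1.75 CPM pooled) and 0 counts over the 3 female vehicle libraries, at least 18.2-fold higher when set against a floor of 3 counts over the vehicle group. In males it had 80 counts with tamoxifen (1.62 CPM pooled) and 3 with vehicle (0.0488 CPM pooled), a ratio of 33.1 (exact Poisson 95% interval 10.9 to 164). It lay above every same-sex vehicle library in 8 of 8 tamoxifen libraries (adjusted p = 0.00105). Egr1 rose by 0.83 ± 0.14 (SE, adjusted p = 0.033), from 31.2 ± 8.5 (SD, n = 3) to 50.8 ± 14.3 CPM (SD, n = 4) in females and from 26.2 ± 3.47 to 50.7 ± 8.14 CPM (SD, n = 4 each) in males. Zbtb16 fell by 1.33 ± 0.17 on the log2 scale (SE, adjusted p = 0.00167), Banp fell by 0.48 ± 0.06 (adjusted p = 0.00161), and both lay below every same-sex vehicle library in 8 of 8 tamoxifen libraries. The deiodinase gene Dio2, whose enzyme makes active thyroid hormone (-0.58 ± 0.10), the folliculin-interacting Fnip2 (-0.36 ± 0.06) and the kinase Map3k13 (-0.30 ± 0.04) also fell.

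In retina females the growth arrest gene Gadd45a rose (0.66 ± 0.11) and Map3k13, Banp, Hif3a (-0.93 ± 0.16) and Dio2 fell, with Wnt7b the other gene past the threshold (adjusted p = 0.0371). With 1 library left out, the call of Map3k13 ended without animal 954, 955 or 958 (adjusted p up to 0.0724). The calls of Banp, Wnt7b, Gadd45a, Hif3a and Dio2 ended in 9, 9, 10, 11 and 12 of 15 such fits, in each case without 952, 953, 954, 955, 957, 958, 959 or 965 (up to 0.338 for Dio2). The others were 962 for Banp, 951 for Wnt7b, 951 and 962 for Gadd45a, 951, 962 and 963 for Hif3a, and 962, 963, 964 and 966 for Dio2. In males edgeR called 0 genes, with 590 at an unadjusted p under 0.05 and 6 by DESeq2; Wnt7b (adjusted p = 0.0519) and Zbtb16 (-1.42 ± 0.23, adjusted p = 0.0551) came closest. For the difference between the sexes edgeR called 0 genes, with 498 at an unadjusted p under 0.05 and 0 by DESeq2. Genes of cholesterol synthesis and uptake had 23 of 26 positive fold changes (median 0.13, camera adjusted p = 9.65e-08; adjusted p = 0.505 with an estimated correlation), 6 of them past the threshold adjusted over the list alone and 0 over all genes by edgeR. Of 20 glucocorticoid responsive genes Zbtb16 fell over all genes and 3 fell adjusted over the list alone (camera adjusted p = 0.000699; adjusted p = 0.582 with an estimated correlation). Of 20 immediate early genes Egr1 rose over all genes, and 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00987; adjusted p = 0.582 with an estimated correlation). Lens genes were higher with tamoxifen (15 genes, median 4.16, camera adjusted p = 9.48e-06; adjusted p = 0.764 with an estimated correlation), with the lens transcript Cryaa at 39.4 CPM in female tamoxifen animal 951, 156 CPM in male tamoxifen animal 959 and 14.1 CPM in male tamoxifen animal 962.

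The retina counts were small and moved with single libraries and settings. DESeq2 called 59 genes with sexes averaged and 32 in females; without the libraries rich in lens transcripts edgeR called 2 in females and 8 in males. The sex-averaged count of 7 was 4 without animal 952, 954, 958, 964 or 966, 15 without 960 and 16 without 963. The female count of 6 was 3 without 951, 2 without 952 or 962, 1 without 953, 957, 959 or 965, and 0 (edgeR) without 954, 955 or 958. The male count was 2 without 953 or 962 and 1 without 955 or 958. Leaving out 1 library ended the call of Egr1 in 8 of 15 fits, of Dio2 in 9 and of Fnip2 in 12, in each case including those without 952, 954, 958, 962, 964, 965 or 966, with adjusted p up to 0.178 for Fnip2, while Wnt7b, Banp and Zbtb16 stayed past the threshold in 15 of 15.

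Across tissues, Zbtb16 and Banp fell in the cortex, the hippocampus and the retina. Cortex and hippocampus shared Arc and Fos among genes that rose, and Banp, Nr6a1, Sik2 and Zbtb16 among genes that fell. Cortex and retina shared Egr1 among genes that rose, and Banp and Zbtb16 among genes that fell. Hippocampus and retina shared 0 genes by edgeR's calls among those that rose, and Banp and Zbtb16 among those that fell. Since the tissues came from shared animals, the overlaps were set, after the data had been seen, against 100 splits of the animals that moved all tissues together, with lists of the same sizes ranked by p. For cortex and hippocampus 1 of 100 splits, the real one included, shared as many genes that rose (highest other 1) and 2 of 100 as many that fell (highest other 4). For cortex and retina the numbers were 4 of 100 (highest other 1) and 3 of 100 (highest other 2), and for genes that fell in hippocampus and retina 1 of 100 (highest other 1). The overlaps are not independent of one another. A joint test of 13790 genes called 2 whose tamoxifen effect differed between tissues. Wnt7b differed most (adjusted p = 1.85e-07), with log2 fold changes of 0.19 in the cortex and 0.02 in the hippocampus, where it was expressed in both treatments. The DESeq2 likelihood ratio test called 29 genes and the stricter filter gave 1. Leaving out animal 951 or 962 gave 4 genes, 955 gave 6, 957 gave 1 and 960 gave 5.

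Genes that oestrogen signalling acts on were examined in every tissue because tamoxifen binds oestrogen receptors. The log2 fold change of the receptor gene Esr1 was -0.10 ± 0.26 in the cortex, -0.28 ± 0.19 in the hippocampus and 0.44 ± 0.17 in the retina (SE, adjusted p = 0.954, 0.767 and 0.546). The membrane receptor gene Gper1, listed as Gpr30, was at -0.41 ± 0.15 in the cortex (adjusted p = 0.34). Pgr, a classical target of the receptor, was at -0.07 ± 0.07, -0.03 ± 0.11 and 0.36 ± 0.13 in the same order (adjusted p = 0.8, 0.961 and 0.496), and Greb1 did not pass in any of the 3 tissues. The sterol enzymes Hmgcs1 and Sqle did not pass either, with log2 fold changes of 0.05 and 0.16 in the cortex. The astrocyte gene Gfap was at -0.02 ± 0.10 in the cortex, 0.18 ± 0.06 in the hippocampus and -0.01 ± 0.11 in the retina, and the microglial gene Aif1 at 0.17 ± 0.15, 0.06 ± 0.11 and 0.42 ± 0.42, none past the threshold (adjusted p of at least 0.432 for Gfap). In the list for reactive gliosis the median was -0.01 in the cortex (camera adjusted p = 0.716).

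Male and female animals were then compared, treatments averaged. In the cortex 7 genes were higher and 5 lower in males among 14680. The X-linked genes Eif2s3x (-0.57 ± 0.03), Kdm6a (-0.47 ± 0.06), Ddx3x (-0.42 ± 0.04) and Kdm5c (-0.26 ± 0.04), which escape X inactivation, were lower in males along with Xist. The list of such genes passed in the cortex with the preset correlation (camera adjusted p = 4.46e-13) and with an estimated correlation (adjusted p = 0.00025), as it did in the hippocampus and retina (adjusted p = 0.0313 and 8.12e-05 with an estimated correlation). Higher in males, beside the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty, were the complement inhibitor Serping1 (0.66 ± 0.11), the matrix protein Fmod (0.51 ± 0.08) and the ubiquitin ligase adaptor Kctd10 (0.35 ± 0.05). Without animal 957 the calls of Fmod (adjusted p = 0.0505) and Kdm5c (adjusted p = 0.0556) ended. Meningeal and fibroblast genes were higher in males as a list (1 of 15 over all genes and 12 adjusted over the list alone, median 0.36, camera adjusted p = 1.01e-12; adjusted p = 0.152 with an estimated correlation). DESeq2 called 33 genes and the fit with all 15 libraries 15; leaving out animal 951 gave 21 and 963 gave 20, and no filter on low counts gave 27.

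In the hippocampus 1630 genes were higher and 1092 lower in males, most of them by a small amount, with a median absolute log2 fold change of 0.24. Beyond sex-linked genes, the largest differences included the sarcomere protein gene Tcap (1.38 ± 0.24), the carbonic anhydrase Car13 (-1.19 ± 0.27), the transcription factor gene Six3 (-2.12 ± 0.62) and the vasopressin receptor gene Avpr1a (-1.21 ± 0.37; log2, male minus female, ± SE). The call of Avpr1a ended without animal 953, 954, 955, 957, 959, 960, 961, 963, 964 or 966 (adjusted p up to 0.0956) and that of Six3 without 958, 961, 963 or 964 (up to 0.091). Of 5 blood genes 4 were higher in males over all genes and 4 adjusted over the list alone (median 0.81, camera adjusted p = 0.0162; adjusted p = 0.583 with an estimated correlation), among them the haemoglobin beta chain gene Beta-s (1.03 ± 0.20, adjusted p = 0.00545). Among 21 microglial genes 7 rose over all genes and 7 adjusted over the list alone, among them C1qc (0.46 ± 0.07) and Trem2 (0.50 ± 0.08; camera adjusted p = 0.00117; adjusted p = 0.118 with an estimated correlation). Of 32 nuclear-encoded genes of oxidative phosphorylation 12 were higher over all genes, and adjusted over the list alone 18 were higher and 1 lower (camera adjusted p = 2.06e-05; adjusted p = 0.818 with an estimated correlation). Each library's deviation from the tissue mean correlated over genes with GC content, with Spearman correlations from -0.6 to 0.262 in females and from 0.192 to 0.479 in males. With transcript length the correlations ran from -0.112 to 0.533 in females and from -0.534 to -0.0598 in males. The count was 1520 without animal 954, 1521 without 955, 1527 without 957 and 1477 without 963. After removal of a smooth trend on GC content and length it was 1058. Whether the genes and lists named here stayed past the threshold after that removal was not tested.

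**Figure D3:**
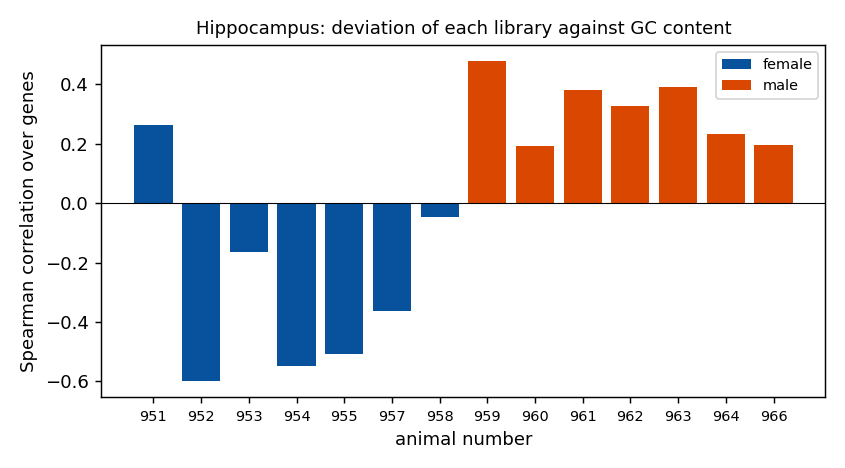
Spearman correlation over genes between GC content and the deviation of each hippocampus library from the mean of all 14, 1 bar per animal number, coloured by sex. All 7 male bars lie above 0, between 0.192 and 0.479, and 6 of 7 female bars lie below 0, the exception being animal 951 at 0.262.

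In the retina 13 genes were higher and 9 lower in males among 14781. Kdm6a (-0.81 ± 0.05), Eif2s3x (-0.60 ± 0.06), Kdm5c (-0.55 ± 0.05) and Ddx3x (-0.43 ± 0.04) were lower in males. The pigment epithelium gene pair Mfrp (1.18 ± 0.23) and C1qtnf5 (1.17 ± 0.23), which overlap in the genome so that their reads cannot be told apart here, were higher in males, as were the matrix protein Ogn (0.67 ± 0.11), the Wnt antagonist Sfrp1 (0.96 ± 0.18) and the Wnt secretion factor Wls (1.04 ± 0.19). Leaving out 1 library ended the call of Mfrp in 10 of 15 fits and of C1qtnf5 in 11, both without animal 951, 952, 954, 955, 957, 960, 962, 963, 965 or 966 and C1qtnf5 also without 961 (adjusted p up to 0.146). It ended that of Sfrp1 without 954, 955, 957, 960, 962, 963, 965 or 966 (up to 0.111), of Wls without 952, 954, 955, 957, 960, 962, 965 or 966 (up to 0.0953) and of Ogn without 954 or 957 (up to 0.0609). Of 18 pigment epithelium genes 12 rose adjusted over the list alone and 0 over all genes (edgeR; median 0.87, camera adjusted p = 2.53e-07; adjusted p = 0.283 with an estimated correlation). DESeq2 called 121 genes, no filter on low counts gave 47, and without the libraries rich in lens transcripts the count was 63. Leaving out animal 954 gave 11 genes, 957 gave 12, 962 or 966 gave 13, 960 or 965 gave 14, 958 gave 57 and 959 gave 110.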

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

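The tests of retinal reads, of the clock and of the order of animals, and the fits without libraries rich in choroid plexus or lens transcripts, were chosen only after the results were seen; the tests of library size, thinning, the choroid plexus covariate and the trend on GC content and length were chosen before them.

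Immediate early genes such as Fos and Arc were higher, and Zbtb16, Per2 and Fkbp5 lower, in the cortex of tamoxifen animals. With log2 library size as a covariate the median log2 fold change of the immediate early genes was 0.45, and in males, whose rod genes had a median log2 fold change of -0.77, it was 0.39, which argues against library size and retinal reads as the whole cause. Outputs of the clock moved by 0.012 on the log2 scale relative to Arntl, Clock and Npas2 (95% interval -0.141 to 0.165). The change of Per2 was 0.49 in size. This argues against a shift that moves this difference as much as Per2. A shift of the clock that leaves the difference unchanged was not tested. Treatment followed the animal numbers in 4 runs over 15 animals, so in each tissue an effect of the order of handling or collection cannot be told apart from treatment. A response to tamoxifen is a hypothesis that stays open beside it, since animal numbers need not follow the order of handling.

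Retinal transcripts were present in cortex libraries, with a median log2 fold change of the rod genes of 1.69 in tamoxifen females and -0.77 in tamoxifen males. The list passed by camera with the preset correlation (adjusted p = 3.87e-08 and 0.000534) and in neither sex with an estimated correlation (adjusted p = 0.497 and 0.669), so a shift with treatment was not established. The near-empty cortex library of animal 962, with a total of 4567 counts, entered no main test. Its Spearman correlation over genes with the mean retina profile exceeded that with the mean cortex profile by 0.053, a small difference that is consistent with retinal reads there. Whether the other cortex libraries hold reads or tissue from the retina was not settled, and no biological explanation was tested.

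In the hippocampus 2722 genes differed between the sexes, against 12 in the cortex and 22 in the retina. With libraries thinned to a common total 2167 genes were called, and with a choroid plexus score as covariate 4124, which argues against depth and choroid plexus tissue as the cause. After removal of a smooth trend on GC content and length the count was 1058, under 50% of the original, so a bias of the libraries with GC content or length, which were removed together and not told apart, may account for a large part of these calls. Sex followed the animal numbers in 2 runs, so a batch that follows the numbers cannot be told apart from sex. A biological sex difference in the hippocampus stays open for the rest and was not separated from it.

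A single library stood apart in 5 of 95 groups of 4 libraries tested, close to the 1 in 20 that chance gives over all of them. All flags but that of Atp10a were in the tissue markers Ttr and Cryaa. Ttr was tested only in the cortex and hippocampus and Cryaa only in the retina, in at most 4 groups of a tissue. The pooled share therefore hides that the flags were concentrated in these markers, and it does not decide whether chance gave those flags. Ttr was at 1900 CPM in hippocampus female tamoxifen animal 951 and at 71.6 to 99.8 CPM in the others of its group. Ttr was at 1020 CPM in hippocampus male tamoxifen animal 962 and at 37.5 to 126 CPM in the others. Atp10a was at 13.2 CPM in hippocampus female tamoxifen animal 954 and at 9.58 to 9.87 CPM in the others. Cryaa was at 39.4 CPM in retina female tamoxifen animal 951 and at 0 in the others. Cryaa was at 156 CPM in retina male tamoxifen animal 959 and at 0 to 14.1 CPM in the others. The tamoxifen effects on Wnt7b (adjusted p = 1.85e-07) differed between tissues by edgeR's joint test. The difference of the tamoxifen effect between the sexes passed in 9 gene lists in the cortex, 4 in the hippocampus and 8 in the retina by camera, and in 0 of them with an estimated correlation (smallest adjusted p = 0.459, 0.777 and 0.48 with an estimated correlation).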

How the results depend on the processing

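The fits without libraries rich in choroid plexus or lens transcripts, with the mean level of rod genes as covariate and without animals 953 and 955 were chosen after seeing the data. No named gene that passed the threshold in the main fit reversed direction in any alternative run, in the contrast where it passed. Named genes that did not pass there were not followed through the alternatives. With 1 animal left out, 1343 values of named genes stayed past the threshold and 353 fell short of it; DESeq2 kept 102 and lost 17. The animal block, which uses the pairing of tissues by animal, left 2 genes in the joint test and changed no call. A pseudocount alternative was not run because the values were counts. The cause was not tested for any change below.

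DESeq2 called 176, 101, 29, 7 and 33 genes in the cortex (sexes averaged, females, males, difference of effects, sex), 63, 20 and 17 in the hippocampus (sexes averaged, females, males), 59, 32, 6 and 121 in the retina (sexes averaged, females, males, sex) and 29 in the joint likelihood ratio test. Without a filter on low counts the counts were 11, 6 and 27 in the cortex (males, difference, sex) and 15, 2 and 47 in the retina (sexes averaged, males, sex). A mean of at least 1 CPM gave 1 in retina females and 1 in the joint test. The additive model gave 5 in the hippocampus with sexes averaged. Fits on the contrasted groups gave 5 in hippocampus females, 0 in retina females (edgeR) and 1 in retina males. All 15 cortex libraries gave 1 for the difference of effects. Without libraries rich in choroid plexus transcripts the cortex gave 35 and 13 (sexes averaged, females) and the hippocampus 0 and 0 by edgeR. The covariate of rod genes gave 6 in cortex females, 7 in cortex males and 1 for the difference. Without libraries rich in lens transcripts the retina gave 2, 8 and 63 (females, males, sex), and without animals 953 and 955 it gave 12 and 2 (sexes averaged, males). With an estimated correlation, 3 of 34 list tests passed for tamoxifen in the cortex, 0 of 24 in the hippocampus and 0 of 26 in the retina, and for sex 2 of 10, 1 of 9 and 2 of 13.

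Leaving out each animal in turn gave 31 to 97 genes in the cortex with sexes averaged, 11 to 61 in females, 4 to 6 in males, 0 to 5 for the difference and 10 to 21 for sex. The hippocampus gave 2 to 11, 0 to 5, 0 to 1, 0 to 0 and 1477 to 3808 in the same order. The retina gave 4 to 16, 0 to 7, 0 to 2, 0 to 0 and 11 to 110, and the joint test 1 to 6.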

Other observations

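The comparisons of counts with other splits of the libraries were planned; the counts by sex without genes on X or Y and the correlations of fold changes between sexes and tissues were chosen after the results were seen.

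Genes of the unfolded protein and integrated stress response passed as lower with tamoxifen in all 3 tissues by camera with the preset correlation. Since the tissues came from shared animals, these passes are not independent, and other splits of the libraries passed lists by this test as well. In the cortex 2 of 20 fold changes were positive, with 0 genes past the threshold by edgeR over all genes and 4 lower adjusted over the list alone (median -0.07, camera adjusted p = 0.00133; adjusted p = 0.459 with an estimated correlation). The chaperone gene Hspa5, named after its values were seen, had log2 fold changes of -0.24 ± 0.07, -0.25 ± 0.08 and -0.24 ± 0.06 in cortex, hippocampus and retina (SE, edgeR adjusted p = 0.133, 0.414 and 0.15). The list gave adjusted p = 0.041 in the hippocampus and 0.00116 in the retina by camera (adjusted p = 0.876 and 0.48 with an estimated correlation). Heat shock genes in the retina had 2 of 12 positive fold changes, with 3 lower adjusted over the list alone (camera adjusted p = 0.00189; adjusted p = 0.505 with an estimated correlation), and Hsph1 was at -0.28 ± 0.05 (adjusted p = 0.0566).

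Genes of MHC class I and antigen processing had 16 of 18 positive fold changes in the cortex (median 0.15, camera adjusted p = 0.00334; adjusted p = 0.595 with an estimated correlation). Myelin and oligodendrocyte genes had 16 of 17 positive fold changes in the hippocampus, with 2 higher adjusted over the list alone (median 0.10, camera adjusted p = 4.48e-05; adjusted p = 0.777 with an estimated correlation). Blood genes in the retina had a median of -0.92, with 4 of 5 lower adjusted over the list alone (camera adjusted p = 9e-05; adjusted p = 0.48 with an estimated correlation).

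In the cortex, 1 of 100 splits gave as many genes as the 89 with sexes averaged, the real one included, and the highest other gave 17. A share of 1 in 100 is the smallest that 100 splits can give. No other split reached the 55 genes in females (1 of 35 splits, highest other 21). For the 12 by sex 2 of 100 splits, the real one included, gave as many, and the highest other gave 96. Of these 12, 9 lay on X or Y, where a difference is given by sex itself. For the other 3 genes 4 of 100 splits gave as many and the highest other gave 92, so chance was not excluded. Shares of splits were not corrected for the number of comparisons made. Nor was chance excluded for the 4 genes in males (2 of 35, highest other 4), the 34 lists for tamoxifen (10 of 100, highest other 41) or the 10 lists for sex (16 of 100, highest other 14). Any split reaches the 0 genes that edgeR called for the difference between the sexes (100 of 100), so that comparison said nothing about chance. Another split called 386 there, which points to a structure of the samples.

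In the hippocampus 3 of 100 splits, the real one included, gave as many as the 10 genes with sexes averaged. Another split gave 104, so chance was not excluded there. No other split reached the 2722 by sex (1 of 100, highest other 1), of which 2620 lay on neither X nor Y (1 of 100, highest other 1). Chance was not excluded for the 2 genes in females (3 of 35, highest other 22). Nor was it for the 24 lists for tamoxifen (43 of 100, highest other 44) or the 9 for sex (33 of 100, highest other 15). Any split reaches the 0 genes that edgeR called in males (35 of 35, highest other 1) and for the difference (100 of 100, highest other 42), so these 2 comparisons said nothing about chance. Splits that called 104 and 22 genes, against 10 and 2, point to a structure of the samples.

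In the retina 3 of 100 splits, the real one included, gave as many as the 7 genes with sexes averaged. Another split gave 168, so chance was not excluded there. For the 22 by sex 2 of 100 splits gave as many (highest other 66). Of these 22, 12 lay on X or Y, where a difference is given by sex itself, and for the other 10 chance was not excluded (2 of 100, highest other 64). It was not excluded for the 6 genes in females (5 of 35, highest other 661), the 26 lists for tamoxifen (32 of 100, highest other 54) or the 13 for sex (11 of 100, highest other 21). Any split reaches the 0 genes that edgeR called in males (35 of 35, highest other 19) and for the difference (100 of 100, highest other 100), so these 2 comparisons said nothing about chance. The split that called 661 genes, against 6, points to a structure of the samples. For the joint test, 9 of 100 splits gave as many as the 2 genes, and the highest other gave 52.

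Over genes, which are not independent replicates, female and male fold changes correlated with r = -0.304 in the cortex, 0.0261 in the hippocampus and 0.277 in the retina. Of 100 splits, 98, 45 and 15 gave a value as high (highest other 0.376, 0.515 and 0.427). The cortex value was negative and lay near the low end of the splits (lowest other -0.329). The sex-averaged fold changes correlated with r = 0.213 between cortex and hippocampus, 0.078 between cortex and retina and 0.136 between hippocampus and retina. A value as high came in 26, 13 and 1 of 100 splits (highest other 0.552, 0.148 and 0.135).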
